A study of Mus musculus with 9 samples.

How the data were processed

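Open chromatin was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, in long-term haematopoietic stem cells (LT-HSCs) and multipotent progenitors (MPPs) sorted from the bone marrow of C57BL/6 mice. Wild-type (WT) cells were compared with cells lacking the retinoid X receptors alpha and beta (KO). The 9 libraries were LT-HSC KO 1, 2 and 4, LT-HSC WT 2 and 3, MPP KO 1 and 2, and MPP WT 1 and 2. Per the labels' protocols, lineage-negative cells from pooled animals were enriched before sorting, and libraries were sequenced as paired reads of 50 nt at a stated mean depth that was not checked here. The labels do not say that replicates came from separate animals or pools, so p-values measure only the spread between these libraries, which may be technical.

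The authors deposited 1 peak list per library, called separately for each library. Peaks were called with MACS2 2.1.1 on the mm10 build, per the submitters' processing notes, which also name cutadapt 1.7, FastQC, Bowtie2, SAMtools 0.1.18, DiffBind 2.6.6, edgeR 3.20.9 and HOMER 4.10.3 without giving their roles. The deposited values for each peak are a fold enrichment (a ratio over background), the −log10 of the p-value and of the q-value, a display score, and the start, end and summit offset. Read counts and the depth of each library were not used here, and depth is therefore unknown. The presence of a deposited peak was taken as the measurement. The −log10 q-value and fold enrichment served to rank peaks within a list, and the q-value also served to filter peaks in 1 alternative. How the authors shifted reads for the Tn5 cut and filtered duplicates is not given in the sources used here.

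The lists held 540767 peaks, all on chromosomes 1 to 19. Peaks that overlapped by at least 1 bp were merged across libraries into 117465 regions, of which 95786 had a peak in 2 or more libraries and were analysed. Genes were 20661 protein-coding genes of GRCm38.p6, whose primary chromosomes are those of mm10. The reference table used here gives gene ends without strand, so transcription start sites were not used. The planned promoter class was replaced by regions within 1 kb of either end of a gene, and the planned nearest start site by the gene that contains the midpoint of the region, or else the nearest gene end within 100 kb. As a check of the build, 4.32% to 5.73% of peaks per library lay within 1 kb of gene ends shifted by 1 Mb, against 19.3% to 41.0% for the true ends. No genome sequence was used, so the planned motif tests were not run, and chromosome X was not analysed here.

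Peak numbers, shares near gene ends and Jaccard indices (shared regions divided by all regions held by either library) were compared by two-sided exact permutation tests. Cell type labels gave 126 labellings, with a smallest p of 0.00794, and genotype labels permuted within cell type gave 60, with a smallest p of 0.0167. Presence in each region was tested by two-sided Fisher's exact tests for cell type over the 52020 regions held by 3 to 6 libraries, and by an exact conditional test stratified by cell type for genotype over 1565 regions able to reach p under 0.05. Both used Benjamini-Hochberg adjustment. A strong separated region was among the 22690 strongest peaks, the length of the shortest list, of every library of one group and had no peak in the full lists of the other. For each of 18 gene lists, holding 346 entries of which 337 were in the reference, excess occupancy was the share of the list's regions held by a library minus the share expected from regions held by as many libraries and in the same class near or away from gene ends. This expectation adjusts for the length of the peak list. It also contains any difference between cell types that all such regions share, so it is not the effect of list length alone. List differences between groups need not be centred on 0. Shares of regions have 95% Wilson intervals, which cover counting error only.

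The lists were HSC identity, HSC quiescence, myeloid priming, lymphoid priming, erythroid and megakaryocyte priming, cell cycle and proliferation, MYC network, MYC target genes, RXR partners and targets, interferon and inflammation, AP-1 and immediate early genes, lipid and mitochondrial metabolism, markers of T, B, mature myeloid, mature erythroid, and stromal and endothelial cells, and a neuronal and hepatic control. They were fixed, with the tests and the rule for naming genes, before the data were examined. For cell types the rule takes, per direction, the 6 genes with most strong separated regions and up to 2 members per list. For genotype it takes the 6 genes with most regions at unadjusted p under 0.05, up to 2 members per list, and within each cell type the 3 genes with most strong separated regions.

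The tests were tested on simulated presence in 20000 regions. With 200 regions made fully separated, both the cell type and the genotype test recovered 100% at unadjusted p and 0% after adjustment, because a separated region cannot go below the smallest p. With 4000 such regions both recovered 100% after adjustment. Among unchanged regions 4.74% (cell type) and 1.43% (genotype) passed unadjusted p in the runs with 200 changed. Of 200 simulated lists of 200 unchanged regions, 2.5% passed for cell type and 4.0% for genotype, and 100% passed in both when presence was raised by 20 percentage points. All simulated libraries had the same detection rates, and the regions of a list were drawn independently of genes. These rates therefore do not cover the difference in list length between cell types or the clustering of regions by gene. Alternatives were a stricter q-value, lists of equal length, 25% coverage or 500 bp windows for shared presence, a 20 kb gene distance, a log2 ratio for lists, a 3 kb gene end distance, each library left out, and pairing by replicate number. Added after seeing the data were an expectation by gene density, the percentile among 2000 random gene lists matched on regions per gene, and leaving out pairs of LT-HSC libraries. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.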

Results

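The series asked how loss of the retinoid X receptors (RXRs), nuclear receptors that pair with retinoic acid, liver X and other receptors, alters chromatin in blood stem and progenitor cells. LT-HSCs are the rare cells that sustain blood formation, and MPPs are their more proliferative descendants. The 5 LT-HSC libraries (3 KO, 2 WT) held 22690 to 71586 peaks and the 4 MPP libraries (2 KO, 2 WT) 78189 to 86353. Of the 95786 regions held by 2 or more libraries, 13908 were held by all 9, and 51.0% of these lay within 1 kb of a gene end (95% Wilson interval 50.2% to 51.9%), against 17.9% of all analysed regions.

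The targeted genes were examined first. Rxra (gene 20181, mm10 chromosome 2, 27676445 to 27763319) had 20 assigned regions, of which the MPP libraries held 17 (KO 1), 18 (KO 2), 16 (WT 1) and 16 (WT 2). The LT-HSC libraries held 0 (KO 1), 3 (KO 2), 15 (KO 4), 11 (WT 2) and 4 (WT 3), where their numbers of libraries and class would give 2.42, 6.70, 13.2, 9.25 and 2.31. At Rxrb (gene 20182, chromosome 17, 34031812 to 34038403) a region at the lower-coordinate gene end, 34031478 to 34032428, was held by all 9 libraries. The deleted segments are not given in the sources used here, and a peak outside them does not check the genotype label.

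The first comparison asked how accessible chromatin differs between LT-HSCs and MPPs. Relative to regions of the same class held by as many libraries, regions of HSC identity genes were held more often in LT-HSCs than in MPPs. The excess over expectation was 7.41 ± 5.90 percentage points (SD, n = 5) in LT-HSCs and −9.26 ± 2.06 in MPPs (SD, n = 4). Exact permutation p was 0.00794, the smallest possible, and Benjamini-Hochberg adjusted p was 0.0238. The observed shares of HSC identity regions were 46.3% in LT-HSCs and 67.8% in MPPs, whose lists are longer. Regions of B cell, mature myeloid and lymphoid genes and of MYC target genes differed in the other direction. The excesses of a list sum to 0 over the libraries by construction, so only the difference between groups carries information. Around Myc, which encodes a transcription factor driving growth and proliferation, 7 regions were held by all 4 MPP libraries and no LT-HSC library. Each library nevertheless held close to the number of Myc regions expected from regions of the same class held by as many libraries. That number contains the difference between cell types over all regions. Myc regions were thus like other regions in this respect, which does not show that list length explains them. In all, 16604 regions were held by every MPP and no LT-HSC library, and 230 by every LT-HSC and no MPP library. Of these, 1019 and 153 were strong separated regions.

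Of the 25 HSC identity genes, with 230 regions, 4 had regions held only by LT-HSCs. These were Rarb (2 regions), encoding retinoic acid receptor beta, and Angpt1 (1), a ligand of the Tie2 receptor, with Slamf1 (1), encoding the stem cell surface marker CD150, and Mllt3 (1), a regulator of stem cell maintenance. The last pair lies outside the naming rule and was chosen after its values were seen. The strongest Rarb region (chromosome 14, 16613955 to 16614442) lay inside the gene and the Angpt1 region (chromosome 15, 42683675 to 42684201) 6.96 kb outside it. In the other direction 11 genes of this list had 23 regions held only by MPPs, among them Rarb (4) and Gata2 (3), and 3 genes had both kinds. Among HSC quiescence genes Egr1, an immediate early transcription factor gene, had 1 region held only by LT-HSCs, while 16 genes had 41 regions held only by MPPs, including 5 each at Smad3 and Tgfbr2 of the TGF-beta pathway. Those 41 are 16.1% of the regions of the quiescence list, against 17.3% MPP-only among all analysed regions. That list as a whole differed by 2.94 points (p = 0.603, exact permutation). Over all genes, Gm15501, Nav3 and Tent5c had 2 strong LT-HSC regions each, and Tent5c also had 2 MPP-only regions, 1 of them strong. Cntnap2, Mmrn1, which encodes a platelet and endothelial protein, and Nadk2 had 2 LT-HSC regions of which 1 was strong, and Cntnap2 also had 1 MPP-only region. Pdk4, a kinase that restrains pyruvate oxidation, and Apob had 1 region each.

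Lists with a higher excess over expectation in MPPs, as LT-HSC minus MPP excess in percentage points, were mature myeloid markers (−13.3, exact permutation p = 0.0159, adjusted p = 0.0408), B cell markers (−12.9), lymphoid priming (−6.46), MYC target genes (−6.35) and stromal and endothelial markers (−3.21). The last 4 each had exact permutation p = 0.00794 and adjusted p = 0.0238. Among mature myeloid genes 13 of 14 had regions held only by MPPs, including Itgam (7), encoding CD11b, and Mrc1 (4), the macrophage mannose receptor. Among lymphoid genes 17 of 18 did, including Ikzf1 (5), which encodes Ikaros, and Notch1 (3). B cell genes Fcrla and Blk had 2 and 1. Of the 26 MYC target genes with regions, 10 had 18 regions held only by MPPs, led by Odc1 (5) of polyamine synthesis and including the amino acid transporter gene Slc7a5 (1), and none had an LT-HSC region of this kind. Those 18 are 17.3% of the regions of the MYC target list, the same share as MPP-only regions have among all analysed regions (17.3%), against 39.8% for mature myeloid, 29.3% for B cell, 24.2% for lymphoid and 10% for HSC identity genes. Runx2 and Pecam1 of the stromal list had 7 each. Mature erythroid markers were the other list with a higher excess in LT-HSCs (20.6 points, with observed shares of 46.7% in LT-HSCs and 71.4% in MPPs, exact permutation p = 0.00794, adjusted p = 0.0238), from 21 regions of 6 genes. Of these regions 12 were assigned to Sptb alone. Only 1 of the 21 was held only by LT-HSCs and 3 only by MPPs, and none was a strong separated region. Adjusted over the list alone, the counts of regions were the same as over all regions for HSC identity, with 5 held by LT-HSCs and 23 by MPPs.

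Leaving out libraries and equalising list length moved several of these values. Without LT-HSC KO 4 the differences were −8.01 for mature myeloid (exact permutation p = 0.114), −8.37 for B cell (p = 0.0286), −4.10 for lymphoid (p = 0.0571) and −4.22 for MYC target genes (p = 0.0571), and without LT-HSC WT 2 that for MYC target genes was −5.24 (p = 0.0571). Stromal markers moved to −2.69, −1.96, −1.86 and −2.31 without MPP KO 1, KO 2, WT 1 and WT 2 (exact permutation p = 0.0714 to 0.161). HSC identity stayed between 11.2 and 18.2 without any single LT-HSC library, at the smallest exact permutation p that 4 against 4 libraries allow (0.0286). In lists of equal length lymphoid priming moved to −2.77 (exact permutation p = 0.206) and stromal markers to −9.14 (p = 0.135), while HSC identity (27.2), mature erythroid (41.6), B cell (−50.0), mature myeloid (−27.9) and MYC target genes (−6.70) each had exact permutation p = 0.00794.

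Myeloid priming (−8.19, adjusted p = 0.0794), cell cycle and proliferation (−7.32, adjusted p = 0.0794) and T cell markers (−7.50, adjusted p = 0.0857) did not pass the exact permutation test after adjustment. Of 18 myeloid genes, 15 had 48 regions held only by MPPs, among them Ly86 (9) and Ctsg (4), which encodes the granule protease cathepsin G. Of 25 cell cycle genes 13 had 37, led by Cdk6 (11) and Ccnd1 (7), both encoding regulators of entry into the cell cycle. MPP-only regions were 26.5% of myeloid priming, 20.2% of cell cycle and 31.6% of T cell marker regions, against 17.3% of all analysed regions. Cd28 and Cd4 had 4 each. The remaining lists lay between −3.81 (MYC network, p = 0.175, exact permutation) and 2.96 points (erythroid and megakaryocyte priming, p = 0.405). Within that range were RXR partners and targets (−0.55), interferon and inflammation (0.14), AP-1 and immediate early genes (−1.76), lipid and mitochondrial metabolism (−0.84) and the neuronal and hepatic control (2.65).

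Among the members of these lists with MPP-only regions, the naming rule gives Myc (7) and Bptf (2) of the MYC network, Plin2 (3) and Rara (1) of the RXR list, Tnfaip3 (4) and Nfkbia (4) of the inflammation list, Btg2 (3) and Fosb (2) of the immediate early list, and Ppargc1a (9) and Nrf1 (4) of the metabolism list. In the lists just named, MPP-only regions were 15% (MYC network) to 19.7% (inflammation) of regions, near the 17.3% of all analysed regions. Rhd and Tfrc had 2 each, Ermap 1, Rbfox3 4 and Alb 1. Over all genes, the MPP direction was led by Coq2 (4 strong regions) and by Rftn1, Runx1, a transcription factor required for blood formation, Aopep, Mcf2l and Smad3 with 3 strong regions each. Rftn1 also had 1 strong LT-HSC region. Runx1 had 14 regions held only by MPPs in all, the strongest inside the gene (chromosome 16, 92715476 to 92716169).

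**Figure D1:**
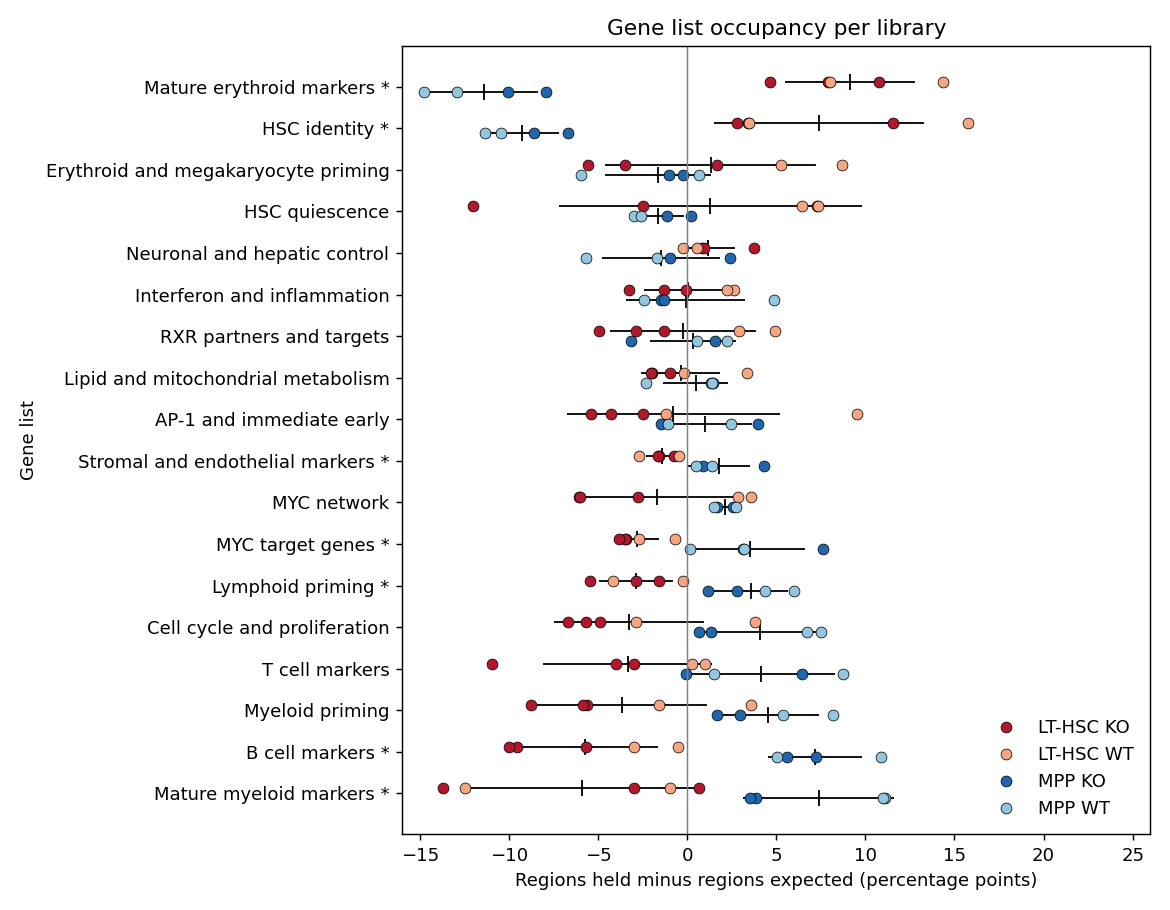
Each point is the excess occupancy of a gene list in 1 library, the share of its regions held minus the share expected, in percentage points; vertical ticks are means and lines 1 SD over 5 LT-HSC (upper) and 4 MPP (lower) libraries, and an asterisk marks adjusted p under 0.05 between cell types. HSC identity lies at 7.41 in LT-HSCs and −9.26 in MPPs, and mature myeloid markers lie at −5.90 and 7.37.

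At the Myc locus (gene 17869, chromosome 15, 61985341 to 61990361) the 15 assigned regions divided by position. The LT-HSC libraries held 2 (KO 1), 6 (KO 2), 6 (KO 4), 6 (WT 2) and 3 (WT 3) of them, where 3.12, 5.12, 7.28, 5.42 and 2.95 were expected. The MPP libraries held 14 (KO 1), 13 (KO 2), 12 (WT 1) and 12 (WT 2), where 12.0, 13.0, 12.7 and 12.3 were expected. Regions at 61983308 to 61983726 and 61984837 to 61985738, beside the lower-coordinate gene end, were held by all 9 libraries. A region at 61928035 to 61928434 was held by 3 LT-HSC and 0 MPP libraries. The 7 regions held only by MPPs lay 9.44 to 81.2 kb beyond the other gene end, and the strongest, 61999562 to 62000032, was a strong separated region (Fisher's exact p = 0.00794, adjusted p = 0.0245, 4 of 4 MPP and 0 of 5 LT-HSC libraries). By definition all 7 were held by KO and WT MPPs alike.

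**Figure D2:**
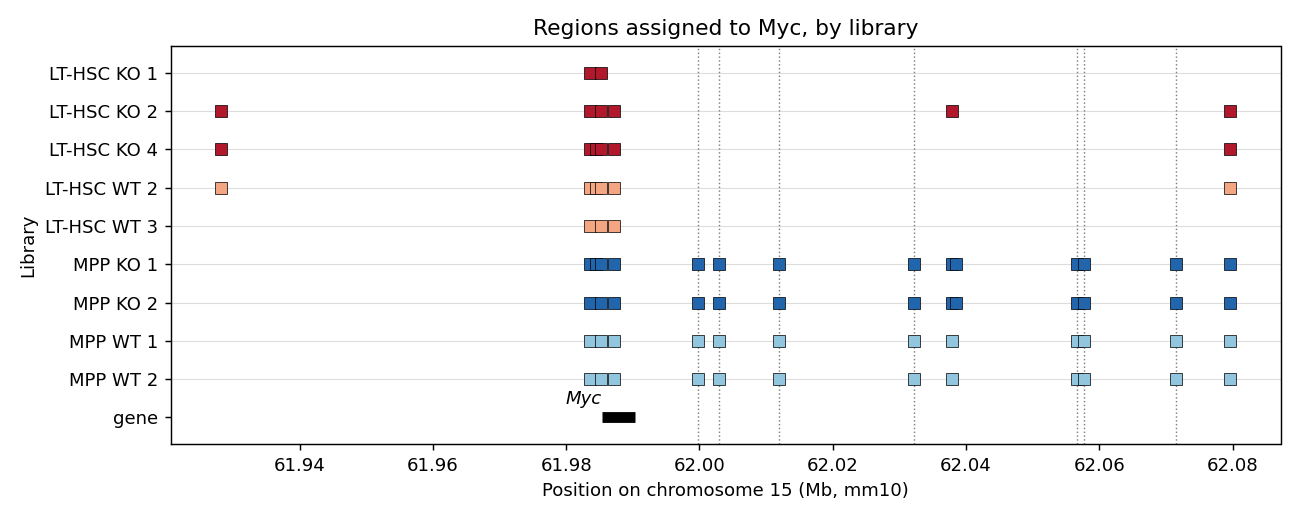
Squares mark the libraries (rows) that held each region assigned to Myc, by position on chromosome 15 in Mb; the black bar is the gene and dotted lines mark regions held by every MPP and no LT-HSC library. The 7 dotted positions hold squares in the 4 MPP rows only.

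Each call of the region test, Fisher's exact with Benjamini-Hochberg adjustment (p = 0.00794, adjusted p = 0.0245), was a complete separation, and at unadjusted p under 0.05 the counts were 1177 for LT-HSCs and 30332 for MPPs. LT-HSC lists were shorter, with 42061 ± 20491 peaks (SD, n = 5) against 82616 ± 3933 (SD, n = 4; exact permutation p = 0.0159), and a list length effect alone, modelled from the library totals, would give 5507 MPP and 0.0024 LT-HSC separations. In lists of equal length the counts were 2854 and 1470, and the LT-HSC count was 379 without LT-HSC KO 1 and 922 without LT-HSC WT 3. The log2 ratio and the gene density expectation each left 3 lists past adjustment, cell cycle moved to 0.99 points in lists of equal length (p = 0.841, exact permutation), and MYC target genes moved to 0.12 on the log2 ratio scale (p = 0.413). Against random gene lists, HSC identity lay at percentile 100, mature myeloid at 0.0, B cell at 0.3, myeloid priming at 0.8 and cell cycle at 1.65, but lymphoid priming at 5.1, MYC target genes at 6.45, stromal markers at 37.1 and mature erythroid markers at 96.05. The last list had exact permutation p = 0.0556 on the log2 ratio scale (0.32).

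Peak sets overlapped more within than between cell types on average, most of all among MPPs. In lists of equal length, MPP pairs averaged 0.855 within and 0.807 across genotypes, and LT-HSC pairs 0.610 and 0.586. Some LT-HSC libraries overlapped MPP libraries more than other LT-HSC libraries. In these lists LT-HSC with MPP pairs reached 0.561, and LT-HSC pairs across genotypes went down to 0.498. The mean Jaccard index was 0.579 within and 0.366 between cell types (difference 0.214, exact permutation p = 0.0159), and 0.681 and 0.478 in lists of equal length (p = 0.00794, the smallest possible). Peaks within 1 kb of gene ends made up 31.3% ± 7.9 of LT-HSC lists (SD, n = 5) and 19.7% ± 0.50 of MPP lists (SD, n = 4; exact permutation p = 0.0159). Exact permutation p was 0.0536 for this share without MPP KO 1, KO 2, WT 1 or WT 2 (11.7, 11.4, 11.4 and 11.6 points) and for peak number without MPP KO 2 (−39310) or MPP WT 1 (−39604). Among the 22690 strongest peaks the shares were 38.2% ± 2.1 and 38.8% ± 0.19, a difference of −0.62 points (exact permutation p = 0.571).

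**Figure D3:**
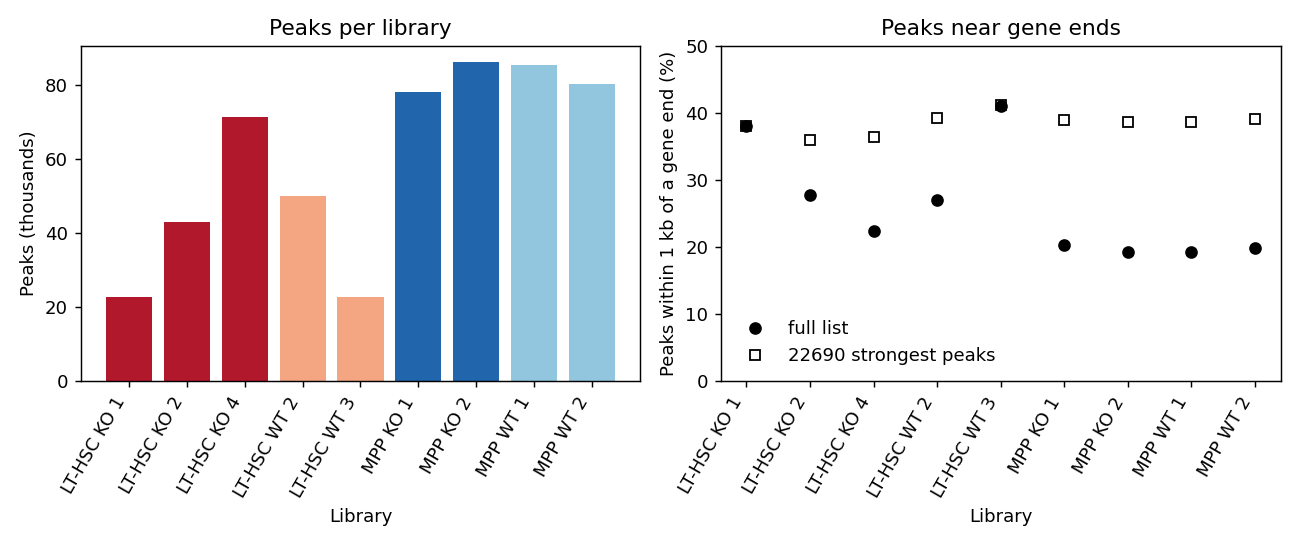
The left panel gives peaks per library and the right panel the percentage of peaks within 1 kb of a gene end, for the full list (filled circles) and the 22690 strongest peaks (open squares). MPP lists hold 78189 to 86353 peaks, LT-HSC lists 22690 to 71586, and the open squares lie between 36% and 41% in all libraries.

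The second comparison asked how loss of RXRs changed accessible chromatin. No gene list and no region passed adjustment between KO and WT, but this does not measure a lack of effect. The smallest possible exact p is 0.0167, and 6 lists must reach it before any list passes. Of the 1565 regions tested, the 37 and 2 that separated fully were too few for any region to pass. The excess over expectation of myeloid priming genes (−6.07 percentage points, KO minus WT) and of cell cycle genes (−6.15) was lower in KO libraries of both cell types, each at the smallest possible exact permutation p of 0.0167 (adjusted p = 0.15). The observed shares of myeloid priming regions were 16.0%, 29.8% and 59.1% in LT-HSC KO 1, KO 2 and KO 4, 46.4% and 24.9% in LT-HSC WT 2 and WT 3, 86.7% and 90.6% in MPP KO 1 and KO 2, and 92.3% in both MPP WT libraries. In MPPs, 846 regions were among the 22690 strongest peaks of both KO libraries and neither WT library, and 889 the reverse. These differ in rank and not in presence, since all 846 had a peak in both full WT lists and 887 of the 889 in both full KO lists. At least 3 of 5 LT-HSC libraries held 60.9% of the 846 and 7.31% of the 889 among their own strongest peaks. These within-MPP counts have no test, since an exact permutation of 2 against 2 libraries cannot go below p = 0.333.

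For myeloid priming the genotype difference was −7.72 points in LT-HSCs and −4.43 in MPPs, and for cell cycle −6.21 and −6.09. Against random gene lists these 2 lists lay at percentiles 0.25 and 0.15. RXR partners and targets differed by −4.58 (p = 0.05, exact permutation; adjusted p = 0.225), the MYC network by −4.09 (p = 0.0667), MYC target genes by 0.91 (p = 0.75), HSC identity by −0.22 (p = 0.917), HSC quiescence by −3.47 (p = 0.5) and the neuronal and hepatic control by 3.05 (p = 0.05). The other 10 lists lay between −4.27 (T cell markers) and 0.95 (stromal markers), with p from 0.1 to 0.767, and 14 of the 18 lists were lower in KO, as was the median of matched random lists for all 18 (−0.35 to −1.22). In lists of equal length the exact permutation p was 0.0833 for myeloid priming (−7.59) and 0.483 for cell cycle (−3.02), and on the log2 ratio scale it was 0.1 for myeloid priming. Without LT-HSC KO 1 and KO 2 the differences were −3.37 and −4.87 (exact permutation p = 0.111 each), and without LT-HSC WT 3 that for cell cycle was −4.16 (p = 0.0833). Without LT-HSC KO 1, KO 2 or KO 4 they were −5.94, −4.63 and −5.91 for myeloid priming and −6.07, −5.88 and −5.61 for cell cycle, each at exact permutation p = 0.0556, the smallest possible with these libraries.

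By region, 37 were held by all 5 KO and no WT library and 2 by all 4 WT and no KO library (stratified exact p = 0.0167 each, smallest adjusted p = 0.669, with 0 calls after adjustment). One of the 2 WT regions lay inside Rara, encoding retinoic acid receptor alpha, an RXR partner (chromosome 11, 98949656 to 98950027, 22.0 kb from the nearer gene end), and the other 6.80 kb outside Dguok (chromosome 6, 83473154 to 83473666), encoding a mitochondrial nucleoside kinase. Genes with KO regions had 1 each, and of these the rule names Adamtsl1, Bcl3, Cavin3, Ccna1, Cped1 and Crb1. No listed gene other than Rara had such a region. Leaving out any LT-HSC KO library leaves no region able to pass, and without LT-HSC WT 3 the WT count was 25. The KO count was 159 without LT-HSC WT 2, 82 without MPP KO 1, 80 without MPP WT 1 and 60 without MPP WT 2. In lists of equal length the counts were 11 and 10.

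Within LT-HSCs, 1209 regions were held by all 3 KO and neither WT library and 32 by both WT and no KO library, with no test since an exact permutation of 3 against 2 cannot go below p = 0.1. Some splits of these full lists that mix genotypes were larger and more uneven. KO 4 and WT 2 against the rest gave 12114 and 7, and KO 2, KO 4 and WT 2 against the rest gave 7749 and 4. Others were smaller, such as 76 and 22 for KO 2, KO 4 and WT 3 against the rest. By genotype, strong separated regions numbered 17 and 5, among them 1 each in Clcn6, Dpyd and Fam241a for KO and at Actg1, Gemin2 and Itsn1 for WT. The KO-only regions lay outside genes and over 100 kb from any gene end in 21.7% (95% Wilson interval 19.4% to 24.1%). Libraries LT-HSC KO 1 and KO 2 differed from the other LT-HSC libraries: 7.33% and 8.32% of their peaks lay that far from genes, against 5.65% (KO 4), 4.87% (WT 2) and 3.15% (WT 3). The split of KO 4, WT 2 and WT 3 from KO 1 and KO 2 gave 2445 and 2693 separated regions in lists of equal length, where genotype gave 563 and 707. In the full lists the KO count was 5155 without KO 1, 5856 without WT 2 and 14062 without KO 1 and KO 2, and the WT count 84 without WT 2, 993 without WT 3 and 2105 without KO 4.

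**Figure D4:**
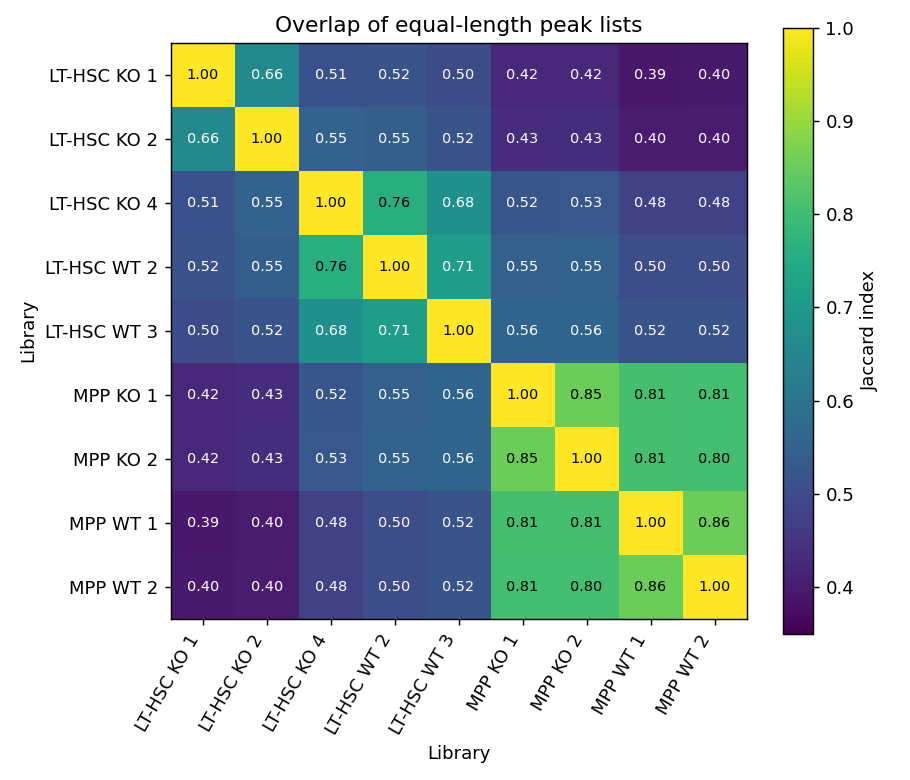
Jaccard index of each pair of libraries after every list was reduced to its 22690 strongest peaks; rows and columns are libraries and colour runs from 0.35 to 1. LT-HSC KO 1 and KO 2 share 0.66 with each other and at most 0.55 with other LT-HSC libraries, and MPP pairs share 0.85 within and 0.81 across genotypes on average.

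Within MPPs, the full lists of each genotype held regions that the other lacked: 2295 regions were held by both KO and neither WT library and 2793 by both WT and neither KO library, and none of either was strong. Pairings that mix genotypes also separated many regions of the full lists. KO 1 and WT 2 against KO 2 and WT 1 gave 585 and 2478, and KO 1 and WT 1 against KO 2 and WT 2 gave 958 and 1417. Without MPP WT 1 the genotype counts were 5338 and 794, without MPP WT 2 3865 and 1076, and without MPP KO 1 and MPP KO 2 the WT count was 4342 and 7125. In the full lists 22.3% of KO-only and 1.93% of WT-only regions were held by at least 3 LT-HSC libraries. The genes with most regions, chosen after their values were seen, were Tjp1, Khdrbs3, Mecom and Wwc2 with 5 each for KO, and Ust, Fmnl2 and Tns3 with 5 each for WT. Mecom is a transcription factor gene needed for stem cell maintenance. Marco, a macrophage scavenger receptor gene, and Igf1 had 4 each for WT. None of the 5 Mecom regions was held by 3 or more LT-HSC libraries.

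**Figure D5:**
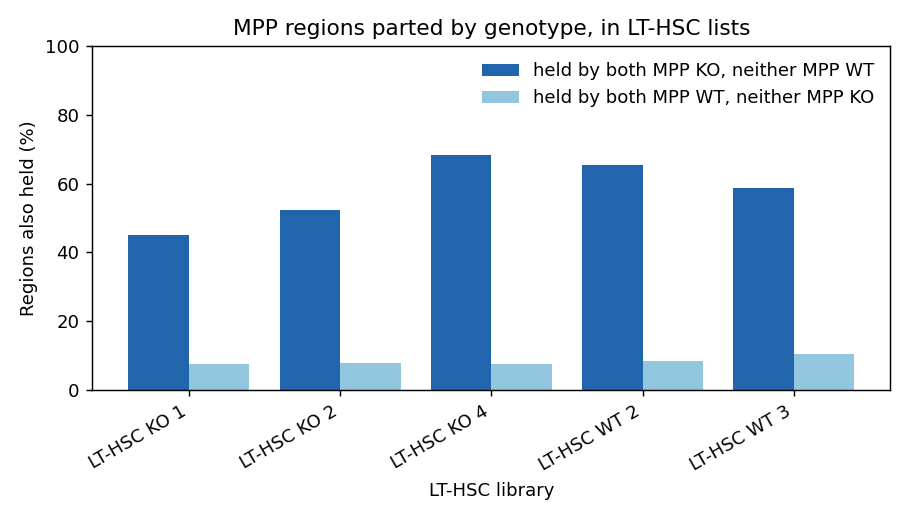
Percentage of MPP regions separated by genotype among the 22690 strongest peaks that each LT-HSC library (x axis) also held among its strongest; dark bars are the 846 regions of both KO MPP libraries and light bars the 889 of both WT MPP libraries. Dark bars run from 45.2% to 68.3% and light bars from 7.65% to 10.5%.

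Mean Jaccard indices within a cell type were 0.554 for libraries of one genotype and 0.594 across genotypes (difference −0.040, exact permutation p = 0.633). In lists of equal length the MPP libraries shared 0.854 to 0.855 within and 0.805 to 0.809 across genotypes. Peak numbers (KO minus WT 4330, exact permutation p = 0.75) and shares near gene ends (−2.19 points, p = 0.567) differed by less than the spread between libraries.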

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

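The tests of explanations in this part were chosen after the results were seen. The outlier and genotype-by-cell-type checks followed fixed rules.

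Among 52 groups of values tested for a sample far from the others, 3 stood out, and chance gives about 1 in 20. MPP WT 2 had the highest excess occupancy of interferon and inflammation genes among MPPs (4.87 points, nearest −1.28) and the lowest of lipid and mitochondrial metabolism genes (−2.29, nearest 1.33). LT-HSC WT 3 had the highest excess of AP-1 and immediate early genes among LT-HSCs (9.51, nearest −1.20). The KO minus WT difference in LT-HSCs minus that in MPPs was −5.63 points for MYC target genes (−1.90 in LT-HSCs, 3.73 in MPPs) and −5.11 for lipid and mitochondrial metabolism (−3.26 and 1.84), each with exact permutation p = 0.0333 and adjusted p = 0.385 over 26 measures.

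MPP-only regions exceeded LT-HSC-only regions, and chance is excluded for the 16604 MPP-only regions (1 of 100 splits drawn, the real one, highest other 692) and the 153 and 1019 strong regions (highest others 22 and 66), with the same highest values over all possible splits. The 230 LT-HSC-only regions were reached by 4 of the 100 splits (highest other 584) and by 6 of all possible splits, or 4.76%. The highest (6366) was LT-HSC KO 4 with all MPP libraries, a structure that follows list length. That share counts only 1 side of each split. Further splits had 240 to 692 separated regions on their other side, so these splits do not exclude chance for the 230 regions as a whole. With both sides counted, the highest of the other splits was 6366 separated and 66 strong regions. The 16604 MPP-only regions, the 1019 strong ones and the 153 strong regions among the 230 were still above these. Adjusted calls (230 and 16604, highest other 0) and the 7 gene lists (highest other 0) add nothing, since 8258 separations are needed for any call and the gene list count restates the permutation p of each list. For the 1019 strong regions the splits cannot tell shorter LT-HSC lists from cell type, although no other split exceeded 66. The longest LT-HSC list (LT-HSC KO 4, 71586 peaks) was shorter than the shortest MPP list (MPP KO 1, 78189 peaks). Only the real split therefore parts all shorter from all longer lists. The split of LT-HSC KO 4 with all MPP libraries gave 4 strong regions among its 6366. That split also requires a region to be strong in LT-HSC KO 4, so it does not measure a length effect. For the other 15585 MPP-only regions, list length and cell type cannot be told apart, because lists of equal length kept 2854 MPP-only regions in all and depth is unknown, while a model from library totals alone, which rests on assumed detection rates, gives 5507 of the 16604.

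LT-HSC KO 1 and KO 2 lay apart from the other LT-HSC libraries, including KO 4. Shorter lists are argued against by lists of equal length, where their highest Jaccard index with another LT-HSC library (0.554) stayed below the lowest among the others (0.676). Weak peaks are argued against by the 10000 strongest peaks, of which at least 6.03% lay far from genes in both, against at most 3.46% elsewhere. Genotype alone is argued against by KO 4, whose index with the WT libraries was at least 0.676, but only if the label of KO 4 is correct. That label was not checked. At Rxra, KO 4 held 15 regions where 13.2 were expected, and WT 2 and WT 3 were also above expectation. KO 1 (0 against 2.42) and KO 2 (3 against 6.70) were below it. Cells of another type stay open: 0 of 6 marker lists were above every other LT-HSC library in both, but their mature myeloid excess (0.67 and −2.99) and neuronal and hepatic excess (0.85 and 3.75) were above the median of the others, and a preparation batch, untested, may also account for the pattern.

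MPP libraries parted by genotype in the rank of 1735 regions in equal-length lists, where the other pairings gave 429 and 453. List length is argued against, since the pairing of shorter with longer lists is the one that gave 453. With 3 pairings no share under 0.05 can be reached, so genotype and a preparation batch shared by same-genotype libraries cannot be told apart, and the genotype itself stays open as the biological explanation.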

How the results depend on the processing

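The higher mean overlap within than between cell types kept its direction under all alternatives run. So did the excess of HSC identity regions in LT-HSCs and of B cell and mature myeloid regions in MPPs. Of 196 comparisons over single gene lists in designs able to pass the threshold, 147 kept their side of it, 47 lost it and 2 reversed (20 others could not pass by design): cell cycle in lists of equal length (0.99) and MYC target genes on the log2 ratio scale (0.12). Lists of equal length moved the difference in share near gene ends between cell types to −0.62 and the genotype overlap to 0.0168. They moved the LT-HSC and MPP region counts to 1470 and 2854, the KO and WT counts to 11 and 10, the LT-HSC genotype counts to 563 and 707 and the MPP ones to 846 and 889. By construction fewer weak peaks enter. Gene lists past adjustment for cell types fell from 7 to 3 with the log2 ratio and to 3 by gene density, the latter chosen after seeing the data. So were the next settings. Without LT-HSC KO 1 and WT 3 the counts were 2081 LT-HSC regions, 1363 and 4592 strong regions and 0 lists. Without LT-HSC KO 1 and KO 2 the LT-HSC KO-only count was 14062 and the genotype overlap 0.00385. The cause of these moves was not tested beyond the change in samples.

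Leaving out 1 library gave −47937 to −35713 for peak number by cell type and −2456 to 11116 by genotype, and 9.09 to 13.7 and −5.70 to 1.31 points for shares near gene ends. By cell type, exact permutation p was 0.0536 for shares without any single MPP library and for peak number without MPP KO 2 or WT 1. Genotype overlap ran from −0.0931 to 0.00996, LT-HSC regions from 230 to 922, KO regions from 0 to 159 and WT regions from 0 to 25. LT-HSC KO-only and WT-only counts ran from 1243 to 5856 and 35 to 2105, and MPP ones from 2176 to 5338 and 794 to 7125. Lists past adjustment for cell types ran from 0 to 7, where any pass needs 11 of 18 lists at the smallest p without an LT-HSC library and 7 without an MPP library, so the 0 says little on stability. The count of lists for genotype stayed at 0, and the KO region count may reflect library structure, as 4 of the 60 genotype splits gave at least 37 KO regions and 29 at least 2 WT regions, with highest others of 174 and 273, several times the real counts. For regions chance is therefore not excluded. The 0 genotype lists cannot be set against splits, as all 60 gave 0 (highest other 0) and 6 lists at the smallest p are needed.

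Same-numbered libraries did not deviate together (correlations −0.0037, 0.0005 and 0.0075 between cell types, −0.113 and −0.0189 between genotypes). With the replicate number as a block of 3 pairs, whose smallest p is 0.25, peak number differed by −43051 between cell types and −2759 between genotypes, shares near gene ends by 11.1 and 0.38 points, strong regions numbered 261 and 1615, and 0 lists passed. Region tests under the block cannot reach p under 0.05 and were not run, nor were the alternatives for chromosome X and motifs or a test of strong regions in lists of equal length. Unknown depth limits every absence of a peak.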

Other observations

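The test of sharing with LT-HSCs was chosen after the first overlaps were seen, and the test by LT-HSC genotype was fixed before its result was seen.

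Of the genotype-separated MPP regions of the full lists, 2295 were KO-only and 2793 WT-only, where a pairing that mixes genotypes gave 585 and 2478. AP-1 and immediate early genes had 8 KO-only and 4 WT-only regions, 3 of the KO-only ones at Fos. MYC target genes had 3 and 0, at Ncl, Rrp12 and Hk2. Cell cycle genes had 1 and 5, myeloid priming genes 2 and 6, and mature myeloid markers 3 and 8, with 4 of the WT-only ones at Marco and 3 KO-only at Mrc1. HSC identity genes had 7 and 5, with 5 KO-only at Mecom. No test was run on these counts, and the genes were chosen after their values were seen.

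A hypothesis is that the peaks of MPPs lacking RXRs may rank more like those of LT-HSCs. In lists of equal length, where 846 of 846 KO-only regions also had a lower-ranked peak in both full WT lists, 60.9% of KO-only MPP regions were held by at least 3 LT-HSC libraries against 7.31% of WT-only regions, a difference of 53.6 points, where the other pairings of the 4 MPP libraries differed by −2.80 and −8.23. Peaks particular to KO libraries of both cell types are argued against, since the WT LT-HSC libraries also held 58.9% and 65.5% of the KO-only regions, while no LT-HSC library held over 10.5% of the WT-only regions. The KO LT-HSC libraries held 45.2% (KO 1), 52.2% (KO 2) and 68.3% (KO 4) of the KO-only regions. Mean Jaccard indices with LT-HSC libraries were 0.497 and 0.499 for MPP KO and 0.458 and 0.460 for MPP WT. No test over libraries was run on these values. More LT-HSCs in the sorted KO MPP fraction, a shifted sort gate or a shared preparation were not tested and stay open.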
